A study of Mus with 9 samples.

How the data were processed

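RNA sequencing counts of 9 libraries of mouse bone marrow cells were analysed, 3 in each of the groups labelled Vec, CCND2wt and CCND2mut. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra kit. The deposited values are raw read counts per gene, which per the submitters' processing notes came from reads handled with CASAVA 1.8 and fastp, aligned to mm10 with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3. Those notes also name DESeq2 1.20.0. The annotation release and the strand setting of the counting are not given in the sources used here. Samples were joined to groups by their titles, and 0 count columns were left without a group. Totals per library were 15043755 to 17593634 counts. The file held 54532 genes, of which 30980 had a read.

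Genes were filtered with filterByExpr, which left 15660 (12701 of them protein-coding), and scaled by TMM factors. All 9 libraries were fitted in 1 quasi-likelihood model in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with robust dispersion and 6 residual degrees of freedom. The median biological coefficient of variation was 0.246. The comparisons were CCND2wt against Vec, CCND2mut against Vec, CCND2mut against CCND2wt, and the mean of both CCND2 groups against Vec. All p-values of genes and lists come from edgeR or limma unless another tool is named. They were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05, and for members of a list also over that list alone. Standard errors were computed from the fitted model. Sums over groups under 4 counts were given as ratios with a 95% counting interval, or for 0 counts as a lower bound from a floor of 3 counts. Log2 CPM for components and correlations used an added value of 1, and pairs of libraries were compared over genes with a summed count of at least 20.

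A total of 32 gene lists, written before the data were examined, held 834 genes, of which 829 were in the file and 772 were tested. They covered blood cell types, cell division, the cyclin D network, translation, energy, lipid and stress pathways, cell death, inflammation, adhesion, transcription factors and chromatin. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and list p-values were adjusted over the 32 lists.

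The genes named in the text followed a rule. It took Ccnd2, Ccnd1, Ccnd3, Cdk4, Cdk6, Runx1 and Runx1t1. It then took the 10 rising and 10 falling protein-coding genes with the largest log2 fold change past the threshold, with groups that did not overlap and a mean of at least 5 CPM in the higher group. Last, it took up to 4 members with the smallest adjusted p of each called list. The text uses only some of these, and says where a gene was chosen after its values were seen.

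The gene test was tested on simulated data made from the same libraries (15291 genes). For CCND2wt against Vec it called 21 of 97 genes changed 2-fold (21.6%) and 54 of 93 changed 4-fold (58.1%), and 2 unchanged genes, 2.6% of all calls. For CCND2mut against Vec it called 12 of 99 changed 2-fold (12.1%) and 55 of 99 changed 4-fold (55.6%), and 5 unchanged genes, 6.94% of all calls. For CCND2wt against Vec, camera called the changed list and 0 of 20 random lists. Random genes need not move together as members of a written list can, so that this does not show how often camera calls written lists wrongly. With the real libraries grouped across their labels, camera called up to 18 lists for CCND2wt against Vec. It called up to 21 for CCND2mut against Vec and up to 17 for CCND2mut against CCND2wt. Such groupings keep part of the difference between labels, so that these counts do not give the rate of wrong calls either. Most simulated 2-fold changes of single genes were thus not called. The simulation changed few genes, while 18.8% and 51.8% of genes passed in the real comparisons of CCND2wt and CCND2mut with Vec. Adjustment is stricter when few genes change, so that these shares do not measure how many real changes were missed.

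Since the comparisons with Vec share their controls, the correlation of their fold changes was set beside 100 simulations with no change in either group. The comparisons were repeated over the other splits of the same libraries (10 splits of 3 against 3, and 100 for the mean of both groups). Medians by chromosome used 10799 genes with a mean of at least 5 CPM and windows of 10 Mb with at least 10 genes. Alternatives tried were RLE size factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, a fit of only the groups compared, a term for the replicate number, removal of haemoglobin, immunoglobulin and mitochondrial genes, a 2-fold threshold, each replicate left out in turn, and the other list tests. After the data were seen, 3 settings were added: the CCND2wt libraries summed to 1 sample, Vec 1 and CCND2mut 1 both left out, and chromosomes 6 and 15 removed.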

Results

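RNA levels in mouse bone marrow cells were measured by sequencing in 9 libraries that fall into 3 groups of 3. According to the labels, the marrow came from irradiated mice that had received fetal liver cells of embryonic day 12.5 with a knock-in of AML1-ETO, the RUNX1-RUNX1T1 fusion of acute myeloid leukaemia. The donor cells carried a retroviral vector with EGFP that was empty (Vec), held cyclin D2 (CCND2wt) or held cyclin D2 with an alanine in place of a threonine (CCND2mut). Cyclin D2 binds CDK4 and CDK6 and drives cells from G1 into S phase. Total counts were 16663680, 15681554 and 15563499 in Vec 1, 2 and 4, and 17593634, 16896559 and 16640532 in CCND2wt 2, 3 and 4. They were 17126454, 16781579 and 15043755 in CCND2mut 1, 2 and 3. Levels are given as counts scaled to library size (CPM), as mean ± SD over the 3 libraries of a group (n = 3), and fold changes on the log2 scale with their standard error (SE). The labels do not say that the libraries of a group are separate animals, so that the p-values measure only the spread between these samples, which may be technical. Intervals and lower bounds on folds cover counting error only.

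The gene named in the labels was examined first. Ccnd2 (ENSMUSG00000000184; chromosome 6, 127125162 to 127152193 in mm10) stood at 76.2, 79.1 and 86.2 CPM in the libraries labelled Vec. It stood at 7.30, 9.29 and 11.1 CPM in those labelled CCND2wt, and at 12.6, 58.2 and 51.1 CPM in those labelled CCND2mut. Against Vec, Ccnd2 fell by 3.12 in CCND2wt (SE 0.50, edgeR adjusted p = 0.00546), and its value in CCND2mut was -0.99 (SE 0.46, adjusted p = 0.106). The counts at this gene thus went against labels that name added cyclin D2. The species and sequence of the transgene are not given in the sources used here, and a coding sequence of another species need not be counted at the mouse gene. Every direction below is therefore one between libraries labelled Vec, CCND2wt and CCND2mut, not one set by a measured level of cyclin D2.

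The other D-type cyclins and their kinases also differed between the labelled groups. Ccnd1 (chromosome 7, 144929931 to 144939925) fell from 5.64 ± 0.684 CPM in Vec to 1.66 ± 0.298 in CCND2wt and 0.901 ± 0.149 in CCND2mut, and was lower in CCND2mut than in CCND2wt (log2 fold change -0.88, edgeR adjusted p = 0.0355). Cdk4 rose from 214 ± 17.3 to 329 ± 14.7 CPM in CCND2wt and stood at 234 ± 31.2 in CCND2mut. Cdk6 stood at 1316 ± 412 CPM in Vec and 1007 ± 43.1 in CCND2wt (adjusted p = 0.356 in edgeR), and fell to 332.5 ± 98.9 in CCND2mut (-1.99 against Vec, SE 0.287). Ccnd3 fell in CCND2mut against Vec (-0.57, SE 0.179, adjusted p = 0.027 in edgeR), and stood at -0.54 in CCND2wt against Vec (adjusted p = 0.0658 in edgeR). Its difference between CCND2mut and CCND2wt was -0.02 (edgeR adjusted p = 0.922), and was above 0 under some of the other settings. Runx1 fell by 1.05 in CCND2mut against Vec, and Runx1t1 fell by 0.65 in CCND2wt and by 1.07 in CCND2mut. Counts at Runx1 and Runx1t1 can hold reads of the fusion.

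The libraries separated by label. The first principal component held 64.4% of the variance of log2 CPM and the second 18.2%. Between groups, the correlation over genes was 0.9145 to 0.9457 for Vec with CCND2wt, 0.8118 to 0.8775 for Vec with CCND2mut and 0.8218 to 0.8448 for CCND2wt with CCND2mut (genes are not independent replicates). The 3 CCND2wt libraries were closer to one another than those of any other group, with a chi-square of counts per gene of 6.998 to 17.7 against 53.3 to 148 for pairs within the other groups. They differed by more than counting noise, as repeat libraries of 1 sample also can, and were treated as 3 samples without a test of whether they are. Haemoglobin genes took 1.51% of counts in Vec 1, 0.0126% in Vec 2 and 0.356% in Vec 4, and at most 0.131% in each of the other 6 libraries. Immunoglobulin genes took 0.588% in Vec 1 and at most 0.0441% elsewhere.

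**Figure D1:**
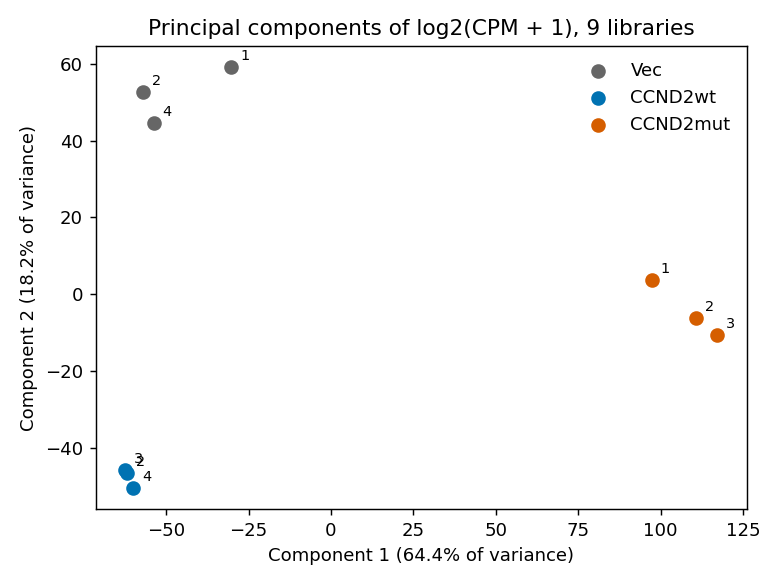
Position of the 9 libraries on the first and second principal components of log2 CPM (axes in component units), with 1 point per library and a colour per labelled group. The components hold 64.4% and 18.2% of the variance, and the 3 CCND2wt points lie closest together.

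The first comparison set marrow labelled CCND2wt against marrow labelled Vec. Genes of cell division were higher in CCND2wt. Of 40 genes of G1/S and DNA replication, 30 rose and 0 fell, with a median log2 fold change of 1.27, and 32 rose adjusted over the list alone. Of 40 genes of G2/M and mitosis, 28 rose and 0 fell, with a median of 1.74, and 37 rose adjusted over the list alone. Pole, the catalytic subunit of DNA polymerase epsilon, went from 38.2 ± 4.33 to 116 ± 6.75 CPM (1.61, SE 0.125). Mcm2, part of the replicative helicase, went from 112 ± 21.2 to 290.5 ± 12.7 CPM, and Foxm1, a transcription factor of mitotic genes, from 26.3 ± 11.8 to 120 ± 6.38 (2.19, SE 0.32). In the list of the cyclin D, CDK4/6, INK4/CIP and RB network, 9 of 30 genes rose and 2 fell (9 and 5 adjusted over the list alone). Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the inhibitor p16INK4A and the p53 activator ARF, went from 0.0830 ± 0.0915 to 19.8 ± 1.87 CPM (7.74, SE 0.813). The RB relative Rbl1 rose by 1.51 (SE 0.186), and the S-phase factor E2f1 went from 32.8 to 92.9 CPM. Camera gave these 3 lists adjusted p = 3.96e-22, 1.01e-20 and 0.045. They had adjusted p = 0.575, 0.575 and 0.578 with an estimated correlation.

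Mast cell genes and genes of the respiratory chain were also higher in the libraries labelled CCND2wt. Of 21 genes of mast cells, basophils and eosinophils, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 1.32. The mast cell protease Mcpt4 (chromosome 14, 56059629 to 56062313) went from 9.07 ± 6.75 to 688 ± 13.3 CPM (6.24, SE 1.04) and the tryptase Tpsb2 from 11.5 ± 8.07 to 649 ± 17.2. Fcer1a, the alpha chain of the IgE receptor, went from 8.72 ± 0.565 to 100.5 ± 20.5 CPM, and Il5ra, the interleukin 5 receptor chain, from 2.61 to 15.1. Of 42 nuclear genes of oxidative phosphorylation, 13 rose and 0 fell (25 and 0 adjusted over the list alone), by small amounts: the complex I subunit Ndufa5 by 0.76 (SE 0.119) and the cytochrome oxidase subunit Cox6a1 by 0.64 (SE 0.112). Camera gave the lists adjusted p = 0.0147 and 5.39e-05, and they had adjusted p = 0.685 and 0.578 with an estimated correlation.

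Genes of mature blood lineages were lower in CCND2wt than in Vec. Of 22 B cell genes 14 fell and 0 rose (19 fell adjusted over the list alone; median -3.56). Of 10 MHC class II genes 7 fell and 0 rose (8 fell adjusted over the list alone; median -2.65), and the invariant chain Cd74 went from 126 ± 126 to 3.81 ± 0.837 CPM (-5.04, SE 0.711). Of 25 maturing neutrophil genes 8 fell and 0 rose (23 fell adjusted over the list alone; median -4.65), among them Padi4, which citrullinates histones, from 109 ± 26.8 to 2.81 ± 0.570 CPM. The chemokine receptor Cxcr2 went from 31.3 ± 36.4 to 2.41 ± 0.937 CPM, with 73.3, 10.7 and 10 CPM in Vec 1, 2 and 4. Of 23 monocyte and macrophage genes 7 fell and 0 rose (17 fell adjusted over the list alone; median -2.84), and of 13 T and NK cell genes 7 fell and 0 rose (11 fell and 1 rose adjusted over the list alone; median -3.11). Prf1, the pore-forming protein of cytotoxic cells, fell by 1.91 (SE 0.309). Of 29 erythroid genes 1 fell, the transferrin receptor Tfrc, and 0 rose (0 adjusted over the list alone; median -2.70).

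Camera called all 6 of these lists, with adjusted p = 6.16e-07, 2.02e-06, 9.68e-07, 8.28e-05, 8.28e-05 and 0.0404 in the order given, and none with an estimated correlation (adjusted p = 0.578, 0.575, 0.578, 0.578, 0.575 and 0.757). Vec 1 held the most haemoglobin (1.51%) and immunoglobulin (0.588%) counts. Without Vec 1 the medians of the B cell, MHC class II, maturing neutrophil, monocyte and macrophage, T and NK cell and erythroid lists were -2.23, -2.17, -1.39, -1.24, -2.27 and -0.36. The members that fell and rose were then 10 and 0, 6 and 0, 4 and 0, 4 and 2, 5 and 0, and 1 and 0. The erythroid list was no longer called without it (camera adjusted p = 0.99). The primary granule list held genes of promyelocytes, not all of which encode granule proteins. Of 18 tested members 3 rose and 7 fell (3 and 10 adjusted over the list alone), with a median of -1.72. The list had camera adjusted p = 0.0156, and adjusted p = 0.578 with an estimated correlation. Without Vec 1 its median was -1.11, with 3 members that fell and 2 that rose of 19 tested. Hk3, a hexokinase of myeloid cells, fell by 2.59 (SE 0.255), while the protease Ctsg rose by 1.85 (SE 0.248).

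Inflammatory, early response and receptor genes fell in part. Of 29 genes of NF-kB and inflammatory cytokines 7 fell and 0 rose (9 fell and 1 rose adjusted over the list alone), including the chemokines Ccl4, from 344 ± 186 to 4.86 ± 0.678 CPM, and Ccl3 (-6.96, SE 0.919). Of 24 immediate early and heat shock genes 6 fell (10 adjusted over the list alone), including the AP-1 subunit Junb, from 4304 ± 236 to 1636 ± 437 CPM, and the nuclear receptor Nr4a1, which fell by 2.05. Of 35 interferon response genes 5 fell (5 adjusted over the list alone), among them Oas1a, a sensor of double-stranded RNA, by 3.32 (SE 0.333). Among 26 cytokine receptor and JAK-STAT genes 7 fell (7 adjusted over the list alone), with the kinase Pim2 at -2.87 and the receptor Flt3 at -1.64. Of 40 haematopoietic transcription factors 7 fell and 1 rose (7 and 1 adjusted over the list alone), with Spi1 (PU.1) at -1.25 and Cebpb at -1.85. Camera gave the 5 lists adjusted p = 0.000222, 0.00275, 0.0404, 0.0105 and 0.0226, and they had adjusted p = 0.578, 0.578, 0.717, 0.578 and 0.575 with an estimated correlation. Glycolysis (5 of 20 fell, 6 adjusted over the list alone; median -0.33), cytosolic ribosomal proteins (6 of 53 fell, 4 adjusted over the list alone; median -0.27) and mitochondrially encoded genes (0 of 13, 0 adjusted over the list alone; median -0.41) were also called lower. Without Vec 1 glycolysis was not called (camera adjusted p = 0.0747 in limma). The camera adjusted p of the 3 lists were 0.0404, 0.00446 and 0.0472, with adjusted p = 0.578, 0.717 and 0.685 with an estimated correlation. The other 12 lists were not called, with camera adjusted p of 0.066 for MYC targets and ribosome biogenesis, 0.0688 for plasma cells, 0.103 for stroma, endothelium and bone, 0.137 for cholesterol synthesis, 0.161 for adhesion and homing, 0.553 for stem and progenitor genes, 0.602 for megakaryocytes and platelets, 0.72 for dendritic cells, 0.72 for unfolded protein and amino acid stress, 0.723 for chromatin regulators, 0.816 for the BCL2 family and 0.833 for p53 targets. Median and mean differed in sign in 5 of these (stem and progenitor, unfolded protein, chromatin, BCL2 and p53).

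The largest single changes included genes that were near 0 in 1 of the groups. Sox21, a transcription factor of the nervous system, had 2 counts in Vec and 5014 in CCND2wt (ratio 2150, 95% counting interval 594 to 17700). The serotonin transporter Slc6a4 (ratio 2130, interval 381 to 84000) and the matrix protein Fbln1 (ratio 1380, interval 248 to 54700) had 1 count in Vec. The aminopeptidase Anpep went from 0.143 ± 0.151 to 125 ± 9.64 CPM and the transcription factor Nfib from 0.128 ± 0.112 to 50.1 ± 4.42. The homeobox gene Nkx2-3 had 0 counts in CCND2wt and was at least 160-fold lower there over the group, with 1.15, 21.1 and 5.26 CPM in Vec 1, 2 and 4. The zinc finger gene Zfp182 had 3 counts in CCND2wt against 1380 in Vec (ratio 537, interval 183 to 2610), and Hoxb4, a homeobox gene of blood stem cells, 1 against 235. Among the 10 largest falls were 4 Y-linked genes, Ddx3y, Kdm5d, Uty and Eif2s3y. Ddx3y stood at 134, 318 and 64.5 CPM in Vec, at 0.635, 0.623 and 0.605 in CCND2wt, and at 27.4, 0 and 0 in CCND2mut. In the last 2 libraries the count of 0 allows up to 0.2 and 0.199 CPM. The X-linked Xist, the RNA of the inactive X chromosome (chosen after its values were seen), stood at 170, 10.7 and 879 CPM in Vec, at 2280, 2110 and 2310 in CCND2wt, and at 4.31, 11.8 and 4.91 in CCND2mut. The groups thus differed in sex-linked genes as well as in label.

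In all, 2938 of 15660 genes passed an adjusted p of 0.05 in edgeR, 1520 higher and 1418 lower in CCND2wt. Groups did not overlap in 48.3% of genes, where chance gives 10% if the libraries are independent samples. Chance would give more if the close CCND2wt libraries were repeats of 1 sample, so that 48.3% need not be an excess. Of the 32 lists, camera called 20, or 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry, a rotation test, 8. Leaving out CCND2wt 2, 3 or 4 left 1044, 1194 or 1019 genes, and summing the 3 CCND2wt libraries into 1 sample, a setting added after the data were seen, left 39.

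**Figure D2:**
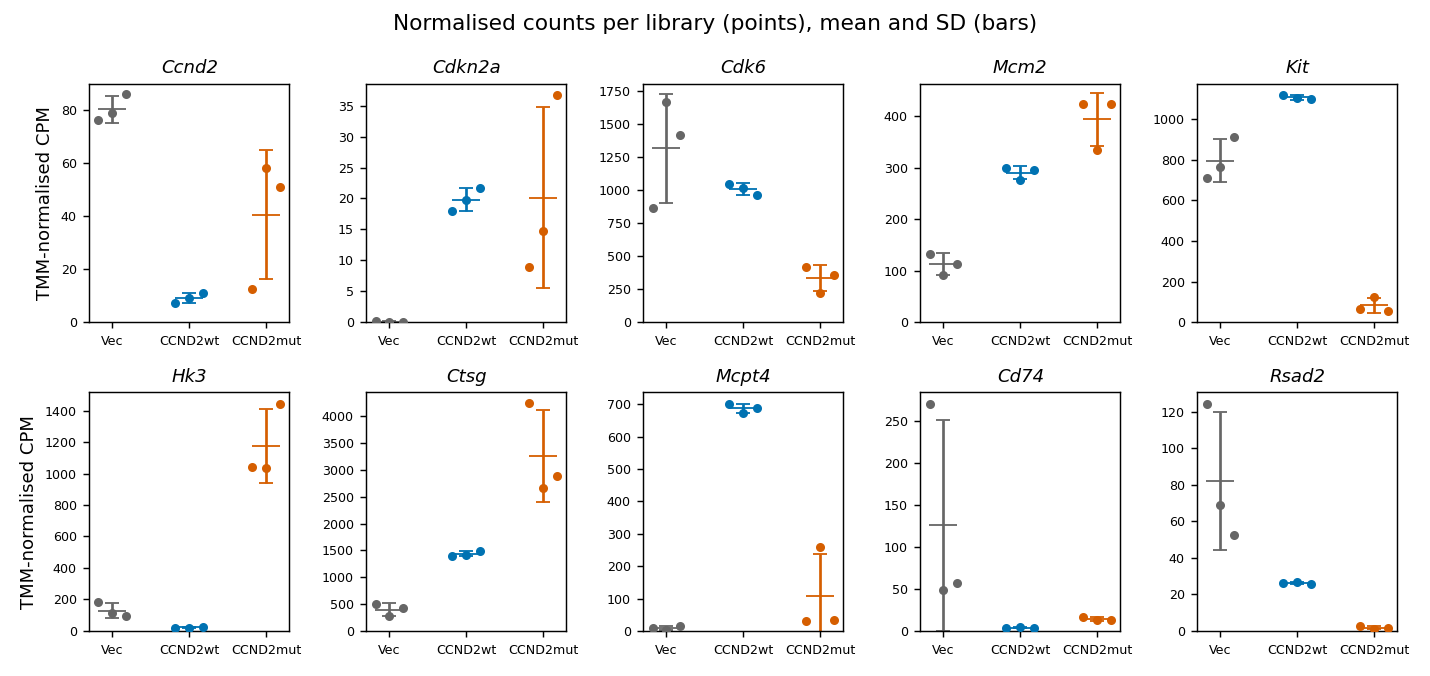
Scaled counts (CPM, vertical axes) of 10 of the named genes in each library (points), by labelled group, with the mean (long line) and SD (short lines, clipped at 0) of the 3 libraries. Ccnd2 is highest in Vec, Mcpt4 in CCND2wt and Hk3 in CCND2mut.

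The second comparison set the libraries labelled CCND2mut against those labelled Vec. Interferon response genes, antigen presentation genes and stem cell genes were far lower in CCND2mut, and genes of cell division, granules, respiration and protein folding were higher. Of 35 interferon response genes 30 fell and 0 rose (30 adjusted over the list alone; median -3.73). Rsad2 (viperin), an antiviral enzyme, went from 81.8 ± 37.7 to 1.65 ± 0.791 CPM (-5.62, SE 0.438), and Oasl2 from 38.7 ± 4.27 to 1.26 ± 0.747. Of 24 stem and progenitor genes 21 fell and 0 rose (22 fell adjusted over the list alone; median -3.67). Kit (chromosome 5, 75574916 to 75656722), the stem cell factor receptor, went from 795.5 ± 105 to 82.0 ± 35.7 CPM (-3.28, SE 0.288), and Angpt1, a ligand of the niche, from 437.5 ± 16.8 to 16.2 ± 7.78. Of 40 haematopoietic transcription factors 21 fell and 3 rose (22 and 3 adjusted over the list alone; median -0.86), among them Meis1 (-5.94, SE 0.85) and Hoxa9 (-5.87, SE 0.653), partners in leukaemic self-renewal. Of 26 cytokine receptor and JAK-STAT genes 13 fell and 2 rose (14 and 2 adjusted over the list alone; median -1.19), with Stat5a at -2.21 and Stat5b at -1.73. Camera gave the 4 lists adjusted p = 1.23e-14, 3.52e-10, 0.0105 and 0.000245, and they had adjusted p = 0.298, 0.298, 0.298 and 0.441 with an estimated correlation.

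Lymphoid, antigen presentation and erythroid genes were lower in the libraries labelled CCND2mut. All 22 B cell genes fell (22 adjusted over the list alone; median -5.20), with the co-receptor Cd22 at -4.67. Of 10 MHC class II genes 9 fell and 0 rose (10 fell adjusted over the list alone; median -3.54), with H2-DMa, a peptide loading factor, going from 62.7 ± 9.23 to 2.16 ± 1.01 CPM. Of 13 T and NK cell genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -3.66), with Prf1 at 0.448 ± 0.107 CPM against 56.2 ± 19.99 in Vec. Of 29 erythroid genes 23 fell and 0 rose (24 fell adjusted over the list alone; median -4.91), with the carbonic anhydrase Car2 going from 920.3 ± 238 to 13.8 ± 18.95 CPM. Camera gave adjusted p = 4.16e-05, 1.1e-05, 0.00235 and 0.0289, with adjusted p = 0.483, 0.298, 0.445 and 0.672 with an estimated correlation. Haemoglobin counts were 0.0248%, 0.00271% and 0.00694% in CCND2mut 1, 2 and 3, and Vec 1 alone held over 1%. Without Vec 1 the erythroid median was -2.24, with 10 members that fell and 1 that rose, and the list was not called (camera adjusted p = 0.141 in limma). The B cell, MHC class II and T and NK cell medians were then -4.04, -2.78 and -2.49. Their members that fell and rose were 20 and 0, 9 and 0, and 7 and 2, and camera still called these lists.

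Myeloid granule genes were higher in CCND2mut. Of 18 primary granule genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 1.94). Hk3 went from 129 ± 44.7 to 1174 ± 234.5 CPM (3.18, SE 0.26) and Ctsg, cathepsin G, from 398 ± 112 to 3266 ± 856 (3.04, SE 0.26). Of 25 maturing neutrophil genes 6 rose and 0 fell (3 rose adjusted over the list alone; median 1.42), among them the granule protein Olfm4, from 23.1 ± 37.1 to 1268 ± 763 CPM, and Cebpe, a factor of late granulocyte genes, from 14.8 ± 21.9 to 177 ± 57.1. In Vec 1, 2 and 4, Olfm4 stood at 66, 1.9 and 1.41 CPM and Cebpe at 40.1, 2.1 and 2.12. Without Vec 1 the maturing neutrophil median was 4.19, with 19 members that rose. The camera adjusted p were 8.76e-05 and 0.0381, with adjusted p = 0.298 and 0.672 with an estimated correlation.

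Cell division, biosynthesis and energy genes were also higher. Of 40 G2/M and mitosis genes 37 rose and 0 fell (38 rose adjusted over the list alone; median 2), and of 40 G1/S and DNA replication genes 34 rose and 2 fell (34 and 2 adjusted over the list alone; median 1.30). Mcm2 rose by 1.81 (SE 0.163) and Foxm1 by 2.47 (SE 0.323). Of 42 nuclear oxidative phosphorylation genes 36 rose and 1 fell (39 and 1 adjusted over the list alone; median 0.79), with cytochrome c (Cycs) at 1.87 (SE 0.149) and Cox6c at 1.60 (SE 0.11). Of 53 cytosolic ribosomal protein genes 30 rose and 1 fell (33 and 1 adjusted over the list alone; median 0.37), led by Rpl8 at 1.29 (SE 0.101), and of 39 MYC target and ribosome biogenesis genes 25 rose and 1 fell (25 and 1 adjusted over the list alone; median 0.59), led by Rrs1 at 1.40. Of 26 unfolded protein and amino acid stress genes 20 rose and 1 fell (20 and 1 adjusted over the list alone; median 1.36): Edem1, which clears misfolded glycoproteins, went from 115.1 ± 10.02 to 447 ± 61.5 CPM, and the lipoprotein receptor Vldlr was the member that fell. Of 20 glycolysis genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; median 1.23), with the pyruvate kinase Pkm at 1.41 (SE 0.138) and Pdk1, an inhibitor of pyruvate dehydrogenase, at -1.90. Of 23 cholesterol synthesis genes 12 rose and 0 fell (12 adjusted over the list alone; median 0.64).

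Camera gave these 8 lists adjusted p = 1.15e-10, 1.86e-08, 8.71e-11, 0.00101, 0.000296, 1.73e-06, 0.00125 and 0.00125 in the order given. With an estimated correlation they were not called (adjusted p = 0.448, 0.448, 0.298, 0.672, 0.448, 0.441, 0.441 and 0.448 with an estimated correlation). Ribosomal protein genes have many near-identical pseudogenes, so that their counts are uncertain. Of 29 p53 targets 14 rose and 6 fell (15 and 6 adjusted over the list alone; median 0.53), with the membrane protein Perp at 281 ± 105 CPM against 2.17 ± 0.895 in Vec and the stress protein Sesn1 at -2.28. Of 12 BCL2 family genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.50). The 4 with the smallest adjusted p, Bax, Pmaip1 (NOXA), Bid and Bak1, promote cell death and rose by 1.37, 4.85, 1.65 and 0.99. Camera gave both lists adjusted p = 0.0381, with adjusted p = 0.304 and 0.298 with an estimated correlation. The other 12 lists were not called, at camera adjusted p of 0.0572 for immediate early and heat shock genes, 0.132 for dendritic cells, 0.132 for mast cells, basophils and eosinophils, 0.132 for chromatin regulators, 0.208 for mitochondrially encoded genes, 0.223 for the cyclin D network, 0.251 for megakaryocytes and platelets, 0.263 for NF-kB and inflammatory cytokines, 0.333 for adhesion and homing, 0.566 for stroma, endothelium and bone, 0.694 for plasma cells and 0.841 for monocytes and macrophages.

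Of the genes named for this comparison, Rpl8 and Cox6c (higher) and Angpt1 (lower) lie on chromosome 15. Mcm2, Foxm1, Cycs, Edem1 and Bid (higher), Hoxa9 (lower) and Ccnd2 (not past the threshold) lie on chromosome 6. Chromosome 6 took 3.95% to 4.22% of counts in the 6 libraries of the other groups and 5.18%, 5.49% and 5.88% in CCND2mut 1, 2 and 3. Chromosome 15 took 4.46% to 5.14% in those 6 libraries and 6.46%, 6.71% and 7.12% in CCND2mut. Relative to the other autosomes, the median log2 fold change of CCND2mut against Vec was 0.43 over 542 genes of chromosome 6 and 0.63 over 436 genes of chromosome 15, while each other autosome lay between -0.15 and 0.09.

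**Figure D3:**
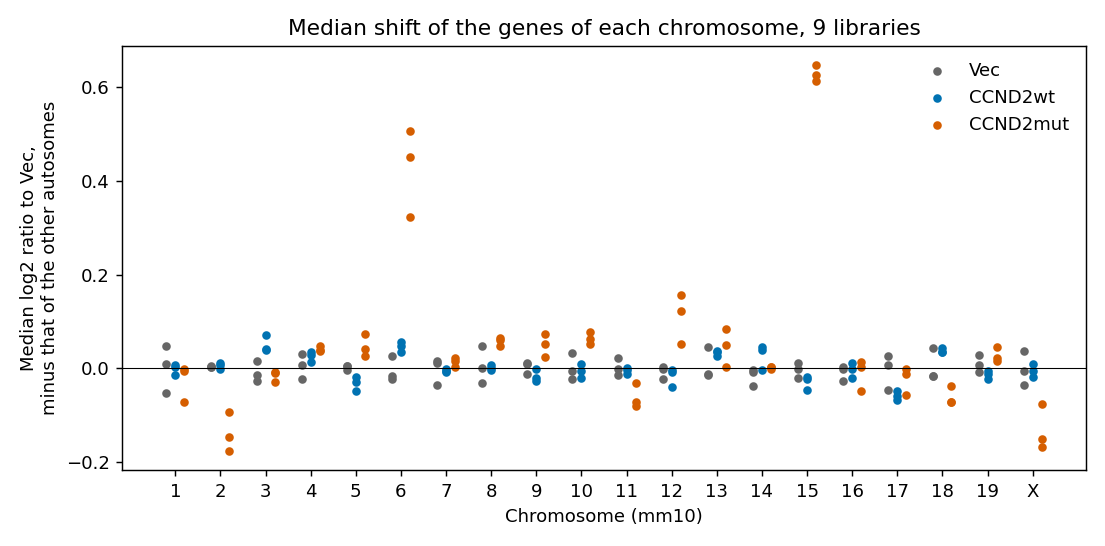
Median log2 ratio of the genes of each chromosome to Vec, relative to the other autosomes (vertical axis), by chromosome (horizontal axis), with 1 point per library coloured by labelled group. The 3 CCND2mut libraries stand at 0.322, 0.506 and 0.451 on chromosome 6 and at 0.613, 0.626 and 0.646 on chromosome 15.

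Among the largest single changes, Retnla, a secreted protein of activated macrophages, had 1 count in Vec and 28354 in CCND2mut (ratio 28600, 95% counting interval 5130 to 1130000), though 38.6 CPM in CCND2mut 1 against 1068 and 779 in CCND2mut 2 and 3. Genes with 0 counts in Vec were the cytochrome P450 Cyp2a5 (at least 1300-fold higher in CCND2mut over the group, with 2.79, 165 and 89.8 CPM in CCND2mut 1, 2 and 3), the lipase Dagla (at least 351-fold) and the adenylate cyclase Adcy1 (at least 238-fold, with 4.01, 19.4 and 23.3 CPM). The stefin Stfa1 went from 0.505 ± 0.817 to 1196 ± 1160 CPM. Its paralogs can share reads. Genes with 0 counts in CCND2mut were the progesterone receptor Pgr (at least 635-fold lower), Sytl4 (at least 324-fold), Ttc8 (at least 166-fold) and Rag1, of antigen receptor recombination (at least 128-fold over the group, with 19.1, 1.49 and 3.14 CPM in Vec 1, 2 and 4). In edgeR 8119 of 15660 genes passed an adjusted p of 0.05, 3906 higher and 4213 lower. The spread in that fit was estimated over all 9 libraries, the close CCND2wt ones included. With only the Vec and CCND2mut libraries in the fit, 6095 genes passed. Groups did not overlap in 56.7% of genes, where chance gives 10% if the libraries are independent samples. Of the 32 lists, camera called 20, or 0 with an estimated correlation (4 at an unadjusted p under 0.05), and fry 23.

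The third comparison set the mutant label directly against the unaltered form. Granulocyte genes were higher in the libraries labelled CCND2mut than in those labelled CCND2wt, and stem cell and interferon genes were lower. Of 25 maturing neutrophil genes 20 rose and 0 fell (22 rose adjusted over the list alone; median 6.02), with Padi4 at 272 ± 68.5 CPM against 2.81 ± 0.570 (6.59, SE 0.31) and Cxcr2 at 166 ± 71.9 against 2.41 ± 0.937. Of 18 primary granule genes 12 rose and 1 fell (15 and 1 adjusted over the list alone; median 3.62), with Hk3 at 5.77 (SE 0.294) and Plac8 at 4.40 (SE 0.349). Of 24 stem and progenitor genes 20 fell and 0 rose (20 adjusted over the list alone; median -3.80), with Kit at 82.0 ± 35.7 CPM against 1107 ± 11.6 (-3.76, SE 0.294) and Hoxa7 at -7.42 (SE 0.742). Of 35 interferon response genes 27 fell and 0 rose (28 fell adjusted over the list alone; median -3.03), with Oasl2 at -4.74 and Zbp1, a sensor of nucleic acids, at -3.99. Camera gave the 4 lists adjusted p = 2.9e-06, 9.78e-07, 1.72e-08 and 5.2e-11, and they had adjusted p = 0.614, 0.405, 0.405 and 0.405 with an estimated correlation.

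Genes of protein synthesis and energy supply were higher in CCND2mut than in CCND2wt as well. The counts that rose and fell were 44 and 0 of 53 cytosolic ribosomal protein genes (46 and 0 adjusted over the list alone; median 0.67), 30 and 0 of 39 MYC target and ribosome biogenesis genes (32 and 0; 0.66), and 19 and 0 of 26 unfolded protein and amino acid stress genes (19 and 0; 1.02). They were 14 and 2 of 20 glycolysis genes (15 and 3 adjusted over the list alone; median 1.48), 27 and 1 of 42 nuclear oxidative phosphorylation genes (29 and 1; 0.46), 8 and 0 of 13 mitochondrially encoded genes (9 and 0; 0.75) and 9 and 3 of 23 cholesterol synthesis genes (9 and 3; 0.46). Hk2, the first enzyme of glycolysis, went from 3.66 ± 0.781 to 268 ± 80.5 CPM (6.19, SE 0.453), and Pkm rose by 1.98 (SE 0.14). Xbp1, a factor of the unfolded protein response, rose by 0.95 (SE 0.12), mt-Nd5 by 1.12 (SE 0.213) and Srebf2, the regulator of sterol synthesis, by 0.93 (SE 0.116). Genes of chromosomes 6 and 15 were shifted in this comparison too, with medians of 0.394 and 0.674 relative to the other autosomes. Hk2 lies on chromosome 6. Camera adjusted p in the order given were 3.45e-07, 1.48e-06, 5.13e-06, 1.22e-05, 7.68e-05, 0.0189 and 0.0337, with adjusted p = 0.673, 0.602, 0.602, 0.405, 0.614, 0.673 and 0.673 with an estimated correlation. Cell division lists were not called: 2 of 40 G1/S genes rose and 6 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.879), and 0 of 40 G2/M genes passed the test in edgeR (0 adjusted over the list alone; camera adjusted p = 0.416). Median and mean differed in sign in 4 uncalled lists (G1/S, immediate early, mast cell and cyclin D network), and the T and NK cell list had both above 0 with a test direction below 0.

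Single genes differed as widely. Retnla had 0 counts in CCND2wt and was at least 11100-fold higher in CCND2mut, and the growth factor Bmp2 at least 815-fold (8.98, 54.4 and 74.0 CPM in CCND2mut 1, 2 and 3). The deiodinase Dio2 had 1 count in CCND2wt and 7076 in CCND2mut (ratio 8330, 95% counting interval 1490 to 329000). Osteopontin (Spp1) went from 0.0734 ± 0.127 to 327 ± 305 CPM. Sox21 had 0 counts in CCND2mut and was at least 1420-fold lower than in CCND2wt, the receptor Gprc5c at least 1170-fold and the dystrobrevin Dtna at least 368-fold. Ccnd2 itself was higher in CCND2mut than in CCND2wt (2.14, SE 0.485, edgeR adjusted p = 0.0072). In edgeR 7360 of 15660 genes passed an adjusted p of 0.05, 3633 higher and 3727 lower. Groups did not overlap in 63.1% of genes. Chance gives 10% if the libraries are independent samples, and more if the CCND2wt libraries are repeats of 1 sample. With the CCND2wt libraries summed to 1 sample 2378 passed, and without CCND2mut 1 camera called 18 lists in place of 11. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05), fry called 19, and camera without the filter on low counts 21.

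The last comparison set the mean of both CCND2 labels against Vec. Genes of cell division were higher and lymphoid, antigen presentation and interferon genes lower in that mean. Camera called 6 lists higher and 10 lower, all lost with an estimated correlation (adjusted p = 0.249 to 0.672 with an estimated correlation). The 6 higher were G2/M and mitosis (37 rose, 0 fell of 40; 38 and 0 adjusted over the list alone; median 1.88), G1/S and DNA replication (32 and 1 of 40; 34 and 2 over the list alone; 1.33), nuclear oxidative phosphorylation (33 and 1 of 42; 36 and 1; 0.61), unfolded protein and amino acid stress (16 and 1 of 26; 17 and 1; 0.76), cholesterol synthesis (7 and 0 of 23; 7 and 0; 0.40) and mast cells, basophils and eosinophils (7 and 1 of 21; 8 and 1; 1.01). Igf2bp3, a fetal RNA-binding protein (chromosome 6), went from 0.345 CPM in Vec to 28.5 in CCND2wt and 82.6 in CCND2mut (7.12, SE 0.212, edgeR adjusted p = 2.88e-06). Cdkn2a stood at 19.8 ± 1.87 and 20.1 ± 14.7 CPM in the groups labelled CCND2wt and CCND2mut (7.75 for their mean against Vec, SE 0.791). All 22 B cell genes and all 10 MHC class II genes fell (22 and 10 adjusted over the list alone; medians -4.16 and -3.28), as did 28 of 35 interferon response genes (29 adjusted over the list alone; median -2.24). Stem and progenitor genes (17 of 24 fell), T and NK cell genes (9 of 13), erythroid genes (24 of 29) and NF-kB and inflammatory cytokines (14 of 29, 1 rose) were lower. So were cytokine receptors and JAK-STAT (14 of 26), haematopoietic transcription factors (16 of 40, 2 rose) and immediate early and heat shock genes (11 of 24, 1 rose). Adjusted over the list alone these 7 counts were 19, 9, 25, 15, 15, 20 and 12. A call for the mean need not hold in both groups. In CCND2wt against Vec the stem and progenitor genes were not called (1 rose and 3 fell, median 0.0741, camera adjusted p = 0.553). The erythroid call was lost without Vec 1 in CCND2wt and in CCND2mut against Vec (camera adjusted p = 0.99 and 0.141).

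The camera adjusted p of the 16 lists lay between 1.87e-18 (G2/M) and 0.0169 (mast cells). In edgeR 6055 of 15660 genes passed an adjusted p of 0.05, 2645 higher and 3410 lower. With the 6 libraries treated as 1 group in the fit 1132 genes passed, and with the CCND2wt libraries summed 1635. Without the filter on low counts camera called 26 lists, with an estimated correlation 0 (3 at an unadjusted p under 0.05), and fry called 21.

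**Figure D4:**
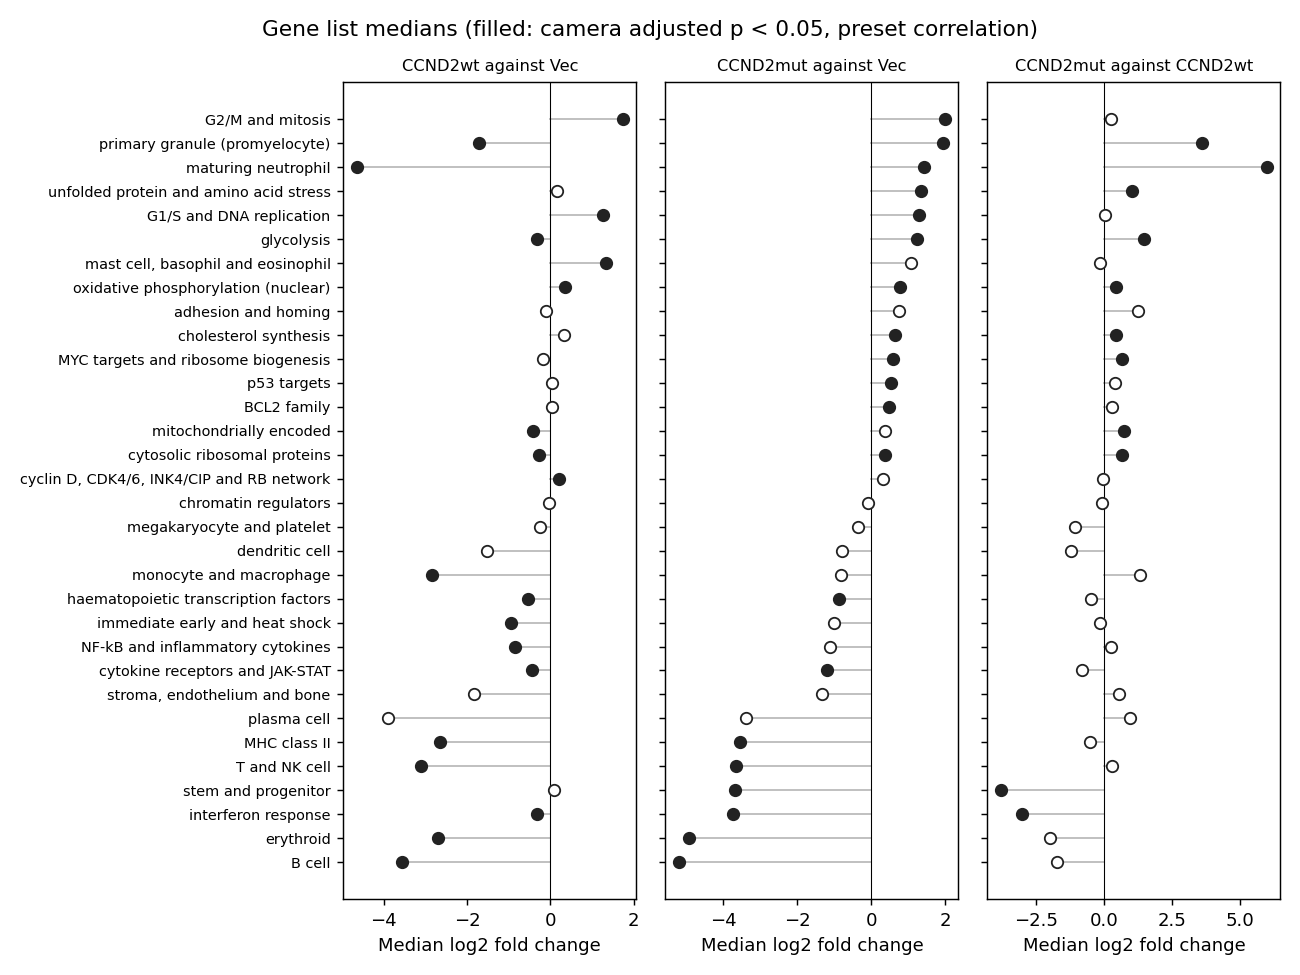
Median log2 fold change (horizontal axes) of each of the 32 gene lists in 3 of the labelled comparisons, with filled points for lists called by camera at the preset correlation. Maturing neutrophil genes stand at -4.65 in CCND2wt against Vec and at 1.42 in CCND2mut against Vec, and G2/M genes at 1.74 and 2.

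Changes in the libraries labelled CCND2wt and CCND2mut overlapped in part. Against Vec, 829 genes were higher in both and 741 lower in both, where independent lists of these sizes would share 379.1 and 381.5. A further 252 genes were higher in CCND2wt and lower in CCND2mut, and 192 the reverse. Over genes, the log2 fold changes correlated with r = 0.167 (rho = 0.253), and 62.3% had the same sign. Simulations without any change drew all 9 libraries, the controls included, from the Vec means. They gave r = 0.504 (0.472 to 0.540 in 100 simulations), a same-sign share of 66.9% and at most 1 gene called in both. Both simulated comparisons share their drawn controls, which by itself gives such an r and same-sign share where nothing changes. The observed r also holds the changes of each group. A value under the simulated one thus does not mean that the effects were less shared than without change. The covariance was 0.461 against a simulated 0.105 (0.0949 to 0.116), a difference of 0.356. The draws used a spread estimated over all groups and treated genes as independent. They hold no difference between Vec libraries that many genes share, so that the simulated covariance may be too low and the difference too large. The 3 control libraries could not be split into parts of at least 2, so that part of any excess may come from the shared controls. Without Vec 1 the correlation was 0.265.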

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

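The weighing of the 3 patterns below used tests chosen only after the results were seen, while the test of CCND2mut against CCND2wt was planned. What marked the following results is that the libraries labelled CCND2wt and CCND2mut were called in opposite directions against Vec, and that the difference between them passed its own test in edgeR or camera. The calls of the 4 lists were lost with an estimated correlation (adjusted p = 0.578 to 0.717 in CCND2wt, 0.298 to 0.672 in CCND2mut and 0.405 to 0.673 for the difference with an estimated correlation, limma). The gene at the centre of the labels, Ccnd2, went against them, so that these directions are between labels. Maturing neutrophil genes had medians of -4.65 (-1.39 without Vec 1) in CCND2wt and 1.42 (4.19 without it) in CCND2mut (median of the difference 6.02), and primary granule genes -1.72 and 1.94 (3.62), or -1.11 and 2.44 without Vec 1. In CCND2wt 3 primary granule members rose and 7 fell. The protease Ctsg was higher than Vec in both groups, at 398, 1438 and 3266 CPM in Vec, CCND2wt and CCND2mut. Glycolysis genes stood at -0.33 and 1.23 (1.48), with the call in CCND2wt lost without Vec 1 (camera adjusted p = 0.0747 in limma), and cytosolic ribosomal protein genes at -0.273 and 0.368 (0.666). Of single genes, Padi4 stood at -5.28 and 1.31 (6.59), Hk3 at -2.59 and 3.18 (5.77), Rgcc, a regulator of cell cycle genes, at -2.19 and 1.96 (4.15), and Pkm at -0.56 and 1.41 (1.98).

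Genes on chromosomes 6 and 15 were higher in CCND2mut than in Vec: 265 of 542 genes rose and 109 fell on chromosome 6, and 247 of 436 rose and 56 fell on chromosome 15, against 21.9% to 33.7% that rose on each other autosome. The lower of the chromosome medians (0.426) restates the pattern and tests nothing further. A small subset of genes was argued against by the lower of the shifts of the lower quartile (0.28), but a subset that lies in some stretches was not tested. Extra copies of both chromosomes needed medians above 0 along their length, and 100% of windows had them (15 of 15 and 9 of 9). With chromosome medians of 0.426 and 0.632 this was close to given, and windows of other autosomes were not scored. Window medians ran from 0.0935 to 0.794 on chromosome 6 and from 0.0454 to 1.07 on chromosome 15. The highest median of another whole autosome was 0.0923. Medians of single windows rest on fewer genes than that of a whole chromosome, so that the lowest windows cannot be weighed against it. Extra copies of the whole of both chromosomes were thus not decided. No DNA was measured, so that a change in copies was not seen directly, and the labels name no group that would explain the pattern.

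In CCND2mut 2 and 3 Ddx3y, Eif2s3y, Kdm5d and Uty together had 0 counts in each, against 986 in CCND2mut 1 and 2316 to 7720 in Vec, while Xist was low but above its floor (11.8 and 4.91 CPM, with 10.7 in Vec 2 and 2110 to 2310 in CCND2wt). Female cells with both X chromosomes active were argued against by the X-linked median relative to CCND2wt, which was at most -0.0591 in these libraries over 330 genes. Cells with 1 X chromosome and no Y chromosome needed a median near 0, and the one farther from 0 was -0.0855. All 9 libraries met this, from -0.129 in CCND2mut 1 to 0.0364 in Vec 2, both with Y-linked counts. The median thus could not tell such cells from those of the other libraries, and this explanation was not decided. The sex of donors and recipients was not used here, mixtures of cells were not tested, and the labels name no group that would explain the pattern.

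Genes of mature blood cells were lower in CCND2wt than in Vec, and Vec 1 held more of several of their most abundant RNAs, chosen here after their values were seen: Hbb-bs at 6920 CPM against 51.7 and 1750 in Vec 2 and 4, Ighm at 934 against 47.2 and 78, S100a9 at 3690 against 124 and 144, and Lyz2 at 1330 against 100 and 123, but less of Dntt of B cell precursors (242 against 350 and 314) and Klf4 of monocytes (183 against 371 and 382). Without Vec 1 the erythroid median moved to -0.364 and the list was not called, so that mature cells in Vec 1 could account for that call. Vec 1 alone did not account for the whole of the medians of B cell (-2.23), maturing neutrophil (-1.39), monocyte and macrophage (-1.24), T and NK cell (-2.27) and MHC class II genes (-2.17). These lists were still called by camera, but the calls decide nothing on the cause. They are lost at an estimated correlation, and camera called up to 18 lists in other splits of the Vec and CCND2wt libraries. Those splits keep part of the difference between labels. Of 25 maturing neutrophil genes 4 then fell, and of 23 monocyte and macrophage genes 4 fell and 2 rose. Mature cells in Vec 2 and 4 were not tested. Of the members, 3 of 29 erythroid, 4 of 25 neutrophil and 4 of 23 monocyte genes are held by another list, and 0 of the B cell, T and NK cell and MHC class II genes. Prf1 stood at 72.5, 62.1 and 33.9 CPM in Vec 1, 2 and 4 and Cd74 at 271, 49.2 and 57.1, the labels state no gate that excludes mature cells, and a difference between CCND2wt and Vec in lineage stays open.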

How the results depend on the processing

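The settings that summed the CCND2wt libraries, left out Vec 1 and CCND2mut 1, or removed chromosomes 6 and 15 were chosen only after results were seen. The cause of the changes below was not tested, except that a demand for 2-fold can only lower a count. Of 351 called results of named genes, 351 kept their direction and side of the threshold with RLE factors, 342 of 342 with DESeq2, 334 with limma-voom, 325 without a filter, 320 with a replicate block, 305 of 349 in fits of only the groups compared and 227 with the CCND2wt libraries summed, and 0 turned. Of 67 called list results, 67 were kept with RLE factors, 60 with limma-voom, 50 with fry and 0 with an estimated correlation. With chromosomes 6 and 15 removed 62 of the 67 were kept. Leaving out Vec 1 and CCND2mut 1 kept 60, with 6 lost and 1 turned. Of simulated 2-fold changes 21.6% and 12.1% were called. Few genes were changed in the simulation, which makes the adjusted threshold harder to pass than in the real data. What else limits this was not tested.

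Genes past the threshold in CCND2wt against Vec (2938) were 1636 with a replicate block, 1844 at 2-fold, 39 with CCND2wt summed and 4470 without Vec 1 and CCND2mut 1, and 1019 to 3020 with 1 replicate left out. Between groups, deviations from the group means correlated over genes at -0.0727 to 0.187 for libraries with the same number in their titles. For the other pairs they correlated at -0.214 to 0.259. The highest with the same number were Vec 1 with CCND2mut 1 (0.187) and Vec 2 with CCND2mut 2 (0.153). A pairing of the samples by number was thus neither shown nor excluded. At 2-fold, 5145 were left of 8119 for CCND2mut against Vec, 4617 of 7360 for CCND2mut against CCND2wt and 3156 of 6055 for the mean. Fits of only the groups compared gave 6095 genes for CCND2mut against Vec, 4319 for CCND2wt against Vec and 7721 for CCND2mut against CCND2wt. With CCND2wt summed, 2378 passed for CCND2mut against CCND2wt and 1635 for the mean, and the fit with 2 groups gave 1132 for the mean. Lists called were 0 in each of the 4 comparisons with an estimated correlation. Fry called 8 for CCND2wt against Vec and 19 for CCND2mut against CCND2wt. Without a filter, camera called 21 for CCND2mut against CCND2wt and 26 for the mean, and with 1 replicate left out 13 to 18 for CCND2mut against CCND2wt. The correlation of both effects against Vec was 0.186 to 0.265 with 1 Vec replicate left out. The sign of Ccnd3 between CCND2mut and CCND2wt turned without CCND2wt 4 (0.03), without Vec 1 and CCND2mut 1 (0.0424) and without chromosomes 6 and 15 (0.00442), and ran from -0.11 to 0.052 with 1 replicate left out. The erythroid list in CCND2wt against Vec turned with adjusted p = 0.953 in camera (limma) without Vec 1 and CCND2mut 1, and had adjusted p from 3.04e-08 to 0.99 with 1 replicate left out.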

Other observations

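The split tests in this part were chosen only after results were seen, while the lists and the gene test were planned. Siglecf, a receptor of eosinophils, stood at 5.93 ± 2.56 CPM in Vec, 4.41 ± 0.857 in CCND2wt and 93.1 ± 23.6 in CCND2mut (log2 fold change of the mean of both against Vec 1.77, SE 0.326, and -0.43 for CCND2wt alone, not past the threshold). The eotaxin receptor Ccr3 fell from 3.87 ± 2.66 CPM to 0.805 ± 0.0408 and 0.868 ± 0.226. Dusp2, a phosphatase of MAP kinases, fell from 2698 ± 162 CPM in Vec to 995 ± 85.9 and 316 ± 156 in the libraries labelled CCND2wt and CCND2mut (-2.27, SE 0.283).

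Some lists that were not called held members that moved in both directions, in a comparison where 47% of all tested genes passed the threshold. In CCND2mut against CCND2wt, 15 of 26 adhesion and homing genes rose and 6 fell (camera adjusted p = 0.117 in limma), 6 of 17 megakaryocyte and platelet genes rose and 9 fell (0.397), and 5 of 34 chromatin regulators rose and 11 fell (0.104). Of 29 p53 targets 14 rose and 7 fell (0.0635).

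Each comparison was repeated over the other splits of the same libraries. For 3 against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave 2938, 8119 and 7360 genes for CCND2wt against Vec, CCND2mut against Vec and CCND2mut against CCND2wt, and the highest other split 0 in each, with 589, 977 and 410 genes at an unadjusted p under 0.05 in edgeR. As many genes were called in 1, 1 and 1 of the splits, the labelled one counted. Splits across labels put the difference between labels into the spread within groups, which lowers their gene calls. The 0 of the other splits was thus close to given. For lists the labelled split gave 20, 20 and 11 and the highest other 18, 21 and 17, with as many called in 1, 2 and 9 of the 10 splits. For the mean of both groups against Vec, 4 of 100 splits gave at least the 6055 genes of the labelled one (highest other 8563). The 3 others, with 8563, 6579 and 6563 genes, all set the 3 CCND2mut libraries against the 6 others, so that the labelled division was not the one with the most calls. With Vec still set apart but the other 6 libraries grouped across their labels, 888, 829 and 793 genes were called. For lists, 57 of 100 gave at least the 16 lists of the labelled split (highest other 22). Many of these splits keep part of the differences between labels. Where the reference group held 1 library of each label, 12 to 18 lists were called with Vec 1 in it and 3 to 11 without. The list count thus did not set the labelled split apart. How many lists camera calls where no groups differ was not shown.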
